A study of Homo sapiens with 19 samples.

How the data were processed

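The 19 libraries were made by Smart-Seq2 and sequenced as paired ends. The lysates of A549 monolayers and spheroids gave 16 libraries, 2 for each of 8 groups of culture form and time, and NEE-sampled RNA gave 3 technical replicates. Per the labels, lysate RNA was extracted with a total RNA kit and NEE-sampled RNA with a clean-up kit for small amounts. The deposited files hold raw counts per gene, which the authors made with FastQC, Trimmomatic, HISAT2 and featureCounts on GRCh38, per the submitters' processing notes. The versions, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Genes that overlap on opposite strands and genes with near-identical copies are therefore uncertain. The files list 62700 genes, of which 58207 were placed on GRCh38 by GENCODE release 29. All 37 mitochondrially encoded genes were at 0 in all 19 libraries, so their list could not be tested, and leaving them out changes nothing.

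The counts were used as deposited. Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, its filter on low counts, robust quasi-likelihood F tests and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. The fit of the 16 lysate libraries had 8 groups, 17822 genes, 8 residual degrees of freedom and a biological coefficient of variation of 0.518. It gave each later time against before NEE in each culture, the interaction of culture and time, and spheroids against monolayers before NEE and over the 4 times. The fit for NEE-sampled RNA held its 3 libraries and the 8 monolayer libraries, with 17067 genes, 6 residual degrees of freedom and a coefficient of 0.519, and compared NEE-sampled RNA with monolayers before NEE. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and at an estimated one, adjusted over the lists of a comparison. A list needed 3 members, which left 27 of 28 lists in the lysate fit and 26 in the fit for NEE-sampled RNA. Group levels are means of TMM-scaled CPM with their SD. A fold against a group at 0 was taken against 3 counts over the group.

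Genes were named by a rule. The 8 with the largest fitted change of each sign were taken from protein-coding genes with a symbol, an adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap in CPM between the groups. Up to 4 called members of each list were added by smallest p, without these conditions on type, level and overlap. In the interactions the 5 largest of each sign were to be named. Where fewer than 5 genes were called, the 5 with the smallest p were taken, and the text gives those that a statement needs. MALAT1, NEAT1, GAPDH and ACTB were followed in each comparison. In the 6 comparisons of a later time with before NEE none of these 4 was called (edgeR adjusted p = 1). ATF3, FOSL1 and the leukocyte and keratin genes of replicate 1 of the monolayers before NEE were chosen after their values were seen. The lists, the comparisons, the naming rule and the alternatives but 1 were fixed before the data were examined. Some items are not reported here.

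Reproducibility and coverage were computed in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 on log2(CPM + 1), with detection at 1 CPM, and figures were drawn with matplotlib 3.10.9. The alternatives were RLE and upper-quartile scaling, no filter and a stricter filter (5 CPM in 2 libraries), the replicate number as a block, overall or within culture, DESeq2 1.42.0, fits without the other groups or with all 19 libraries, thinning of the counts to 13626934 per library, a minimum of 2-fold, another pseudocount of 0.1, detection at 5 CPM or 10 counts, and leaving out each library in turn. Summing the 3 NEE technical replicates into 1 library was added after the results were seen. Where a group was left with 1 library, that library was assumed to vary like the other groups.

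The replicate number comes from the labels' batch tag and was taken to pair the lysate samples. Whether it marks a processing batch is not known. For NEE-sampled RNA it numbers technical repeats, so a number shared with a lysate library is not known to mean anything in common. Deviations of same-numbered libraries from their group means had correlations across 10089 genes of −0.278 to 0.498 over 28 pairs, with a median of 0.215, and 19 pairs were above 0.1. The main fit leaves the replicate number out and takes libraries as independent, and the block is an alternative. The value of the overall block is given where it changes a call, and that of the block within culture only for some calls. None of the 171 pairs of the 19 libraries was a duplicate, with a mean chi-square per gene of 17.2 to 950 over genes with at least 20 counts, and of 38.3 to 229 in the 11 pairs within a group. On simulated data calling recovered 5.97% of 2-fold, 67.2% of 4-fold and 87.9% of 8-fold changes for monolayers at 2 h. Cultures over the 4 times had 68.7%, 97% and 97%, and NEE-sampled RNA 8.96%, 71.6% and 90.9%. Of the simulated calls 4.31%, 5.7% and 7.94% were unchanged genes. These rates need not hold for real calls.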

Results

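RNA was sequenced from A549 cells, an established human lung adenocarcinoma line, around nanostraw electroporation (NEE), in which hollow nanoscale tubes and brief electric pulses open cells so that RNA can be drawn from them while they live. Cells grown flat as monolayers or as spheroids, small balls of cells, were lysed before NEE, right after it, 2 h later and 24 h later. Each of these 8 groups had 2 biological replicates, which gave 16 lysate libraries. A separate arm held 3 technical replicates of RNA that NEE had drawn from A549 monolayers. The lysate libraries held 16031034 to 24571083 counts over genes. The NEE-sampled libraries held 13626934 to 18512985, with a median of 14312031. At these depths 3 counts correspond to 0.122 to 0.22 CPM (counts scaled to the library total) in a library. The reads come from PCR without molecular identifiers and are not independent molecules, so the floors and Poisson values given here cover counting error only. No labelled group was handled without NEE, so a change after NEE includes that of handling and of time in culture.

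Replicate 1 of the monolayers before NEE differed in makeup from the other lysate libraries, and it enters every comparison with that group. Transcripts of natural killer and T cells were among them. PRF1, which encodes the pore-forming protein perforin, stood at 204 CPM against 3.88 to 16.6 CPM in the other lysate libraries. PTPRC, the leukocyte common antigen, stood at 91.3 CPM against 1.65 to 5.73 CPM, and GNLY, the cytotoxic granule protein granulysin, at 108 CPM against 1.6 to 9.8 CPM. The epithelial keratin KRT18 was at 932 CPM against 3320 to 8000 CPM, KRT8 at 4070 CPM against 7460 to 16100 CPM and the glycolytic enzyme GAPDH at 1800 CPM against 3570 to 8540 CPM. Against the mean of the other 15 libraries, the median log2 ratio in this library was 1.39 for the extracellular matrix list and −0.98 for the list of NRF2 targets. In the other lysate libraries, natural killer and T cell transcripts stood at a median of 3.71% of their CPM in this library over 19 genes, and whether these are reads exchanged between libraries or RNA of the libraries themselves is not known, so their low levels there are uncertain.

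**Figure D1:**
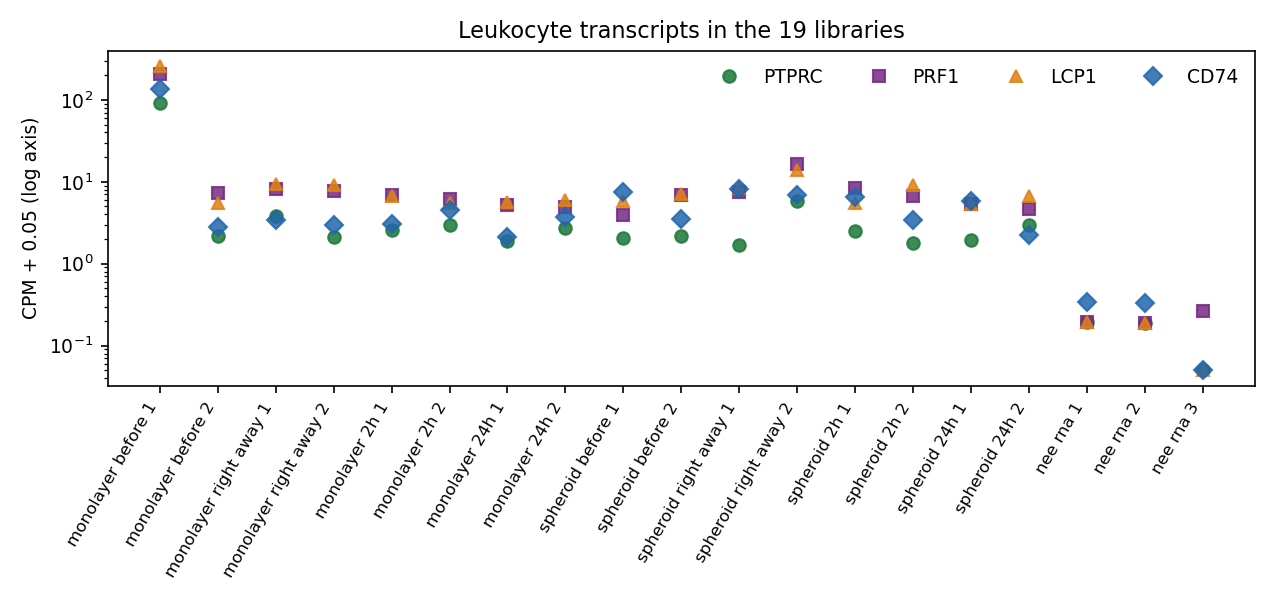
Level of 4 leukocyte transcripts (PTPRC, PRF1, LCP1 and CD74) in each of the 19 libraries, as CPM + 0.05 on a log axis, with 1 point per gene and library. Replicate 1 of the monolayers before NEE lies at 91.3 to 259 CPM, above all other libraries.

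The response to NEE was followed by comparing each later time with the lysates before NEE, within monolayers and within spheroids. In spheroids 2 h after NEE, TIPARP and CYP1B1 rose. TIPARP, an ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor, went from 63.9 ± 1.12 to 429 ± 49.5 CPM (mean ± SD, n = 2 each), a log2 fold change of 2.75 ± 0.22 (SE, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.000151). CYP1B1, a cytochrome P450 enzyme gene controlled by the same receptor, went from 95.4 ± 13.2 to 689 ± 92.5 CPM, a log2 fold change of 2.85 ± 0.35 (SE, edgeR adjusted p = 0.0113). In monolayers at 2 h TIPARP rose from 113 ± 21.7 to 358 ± 26.1 CPM (mean ± SD, n = 2 each), by 1.66 ± 0.21 on the log2 scale (SE, edgeR adjusted p = 0.0399). CYP1B1 in monolayers stood at 362 CPM against 99.5 CPM before, a log2 fold change of 1.86 ± 0.34 that did not pass the test (edgeR adjusted p = 0.715). NFE2L2, which encodes the transcription factor NRF2, had log2 fold changes of 1.38 in monolayers and 1.42 in spheroids and also missed the threshold (edgeR adjusted p = 1 and 0.423). TIPARP (ENSG00000163659) lies on chromosome 3 at 156673235 to 156706770 and CYP1B1 (ENSG00000138061) on chromosome 2 at 38066973 to 38109902 (GRCh38).

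Of 17822 genes tested by edgeR, 1 was called in monolayers and 2 in spheroids at 2 h, all higher. At an unadjusted p under 0.05 there were 605 and 604 genes, and DESeq2 called 53 in monolayers (13 higher, 40 lower) and 39 in spheroids (29 higher, 10 lower). The monolayer call of TIPARP was lost without replicate 1 of the monolayers before NEE (edgeR adjusted p = 0.0606), without replicate 1 of the 2 h monolayers (0.552) and without replicate 2 (0.301). It was also lost in a fit of these 4 libraries alone (edgeR adjusted p = 0.696) and with the replicate block set within each culture (0.0584), while 44 genes were called without replicate 2 of the monolayers before NEE. The spheroid call of CYP1B1 was lost without replicate 1 or 2 of the spheroids before NEE (edgeR adjusted p = 0.57 and 0.251) and without replicate 1 of the 2 h spheroids (0.128), and 8 genes were called without replicate 2 of the 2 h spheroids. With the replicate number as a block, spheroids had 3 called genes at 2 h. TIPARP was the 1 gene called in both cultures, against 0.000112 expected of independent lists (Fisher's exact test, two-sided, p = 0.000112). By DESeq2, 6 genes were called higher in both (Fisher's exact test, p = 1.82e-14), and 0 of the 40 and 10 called lower were shared. Genes are not independent, so these p do not measure reproducibility over libraries.

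Immediate early genes, transcription factors and regulators switched on within minutes to hours of a stimulus, were higher as a list at 2 h in both cultures. In spheroids 22 of the 24 members tested had a positive log2 fold change, with a median of 1.43 (camera set test with Benjamini-Hochberg adjustment, adjusted p = 8e-19, and adjusted p = 0.148 with an estimated correlation). None was called by edgeR over all genes (0 of 24), and 9 were called adjusted over the list alone. FOSB, a subunit of the AP-1 transcription factor, had no count in spheroids before NEE and was at 28.0 ± 31.0 CPM at 2 h, at least 316-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.103). Replicate 1 of the 2 h spheroids stood at 49.9 CPM and replicate 2 at 6.03 CPM, so this bound rests mostly on replicate 1. NR4A1, an orphan nuclear receptor gene, stood at 203 ± 179 CPM against 13.3 ± 1.07 CPM (edgeR adjusted p = 0.132, and 0.0369 with the replicate block). Without replicate 2 of the 2 h spheroids both were called (edgeR adjusted p = 0.00997 for FOSB and 0.00781 for NR4A1). In monolayers 22 of 24 members were positive with a median of 0.92 (camera adjusted p = 4.36e-09, and adjusted p = 0.63 with an estimated correlation), 2 called adjusted over the list alone and 0 over all genes. Both list calls stood with every library left out in turn, with a median of 0.54 in spheroids without replicate 1 of the 2 h spheroids. The floor of 3 counts holds for a whole group throughout, and the list medians did not move with FOSB at its bound.

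**Figure D2:**
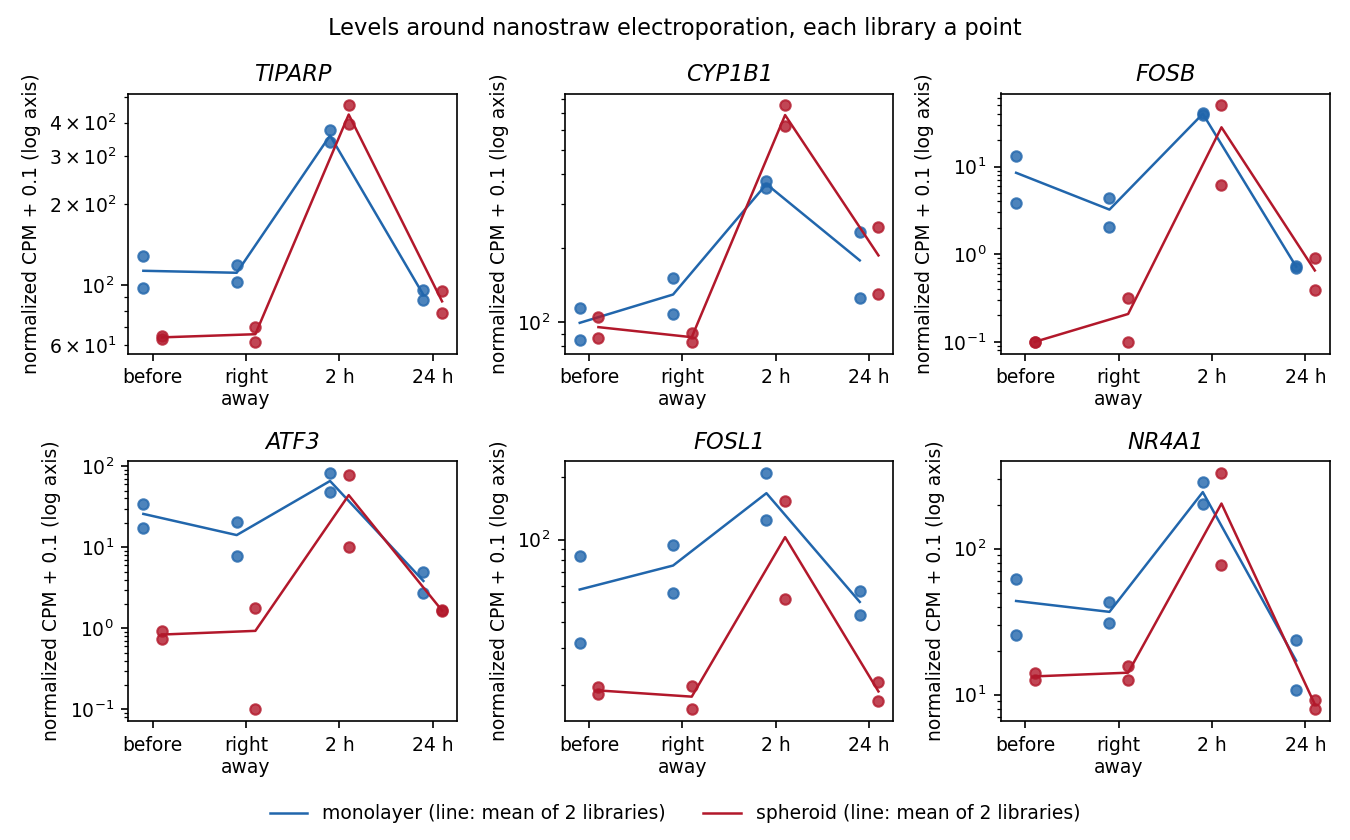
Level of TIPARP, CYP1B1, FOSB, ATF3, FOSL1 and NR4A1 at the 4 times in monolayers (blue) and spheroids (red), as normalized CPM + 0.1 on a log axis, where each point is a library and each line joins the means of 2 libraries. TIPARP goes from 63.9 CPM before NEE to 429 CPM at 2 h in spheroids and from 113 to 358 CPM in monolayers.

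In spheroids at 2 h, targets of YAP and TAZ, coactivators that respond to cell shape and contact, were higher as a list, with a positive log2 fold change in 16 of 19 members and a median of 0.67 (camera adjusted p = 1.8e-08, and adjusted p = 0.148 with an estimated correlation). Of these, 5 were called adjusted over the list alone and 0 over all genes. AMOTL2, an angiomotin family member on this list, stood at 196 ± 117 CPM against 26.8 ± 10.7 CPM (edgeR adjusted p = 0.187, and 0.0322 without replicate 2 of the 2 h spheroids). Nuclear-encoded subunits of the respiratory chain were lower, with 2 of 33 positive and a median of −0.45 (camera adjusted p = 2.47e-09, and adjusted p = 0.357 with an estimated correlation). These calls also stood with each library left out. The other called lists each lost the call with some library left out. ATF4 targets had a median of 0.30 (camera adjusted p = 0.00441, and adjusted p = 0.458 with an estimated correlation), and lost the call without replicate 2 before NEE (0.148) or replicate 1 at 2 h (0.0967). Hypoxia and glycolysis genes had −0.36 (camera adjusted p = 0.000844, and adjusted p = 0.849 with an estimated correlation), which turned to 0.15 without replicate 1 before NEE and was −0.02 without replicate 2 at 2 h. G2/M genes had −0.27 and G1/S genes −0.15 (camera adjusted p = 0.00251 and 0.0295, and adjusted p = 0.849 for both with an estimated correlation). Both lost the call without replicate 2 before NEE (0.21 and 0.686) or replicate 1 at 2 h (0.282 and 0.313). Ribosomal protein genes had −0.14 (camera adjusted p = 0.0401, and adjusted p = 0.999 with an estimated correlation) and lost the call without replicate 1 before NEE (0.593) or replicate 2 at 2 h (0.803). NF-kB targets, at a median of 0.20, were called only with the replicate block (camera adjusted p = 0.101 without and 0.0344 with it).

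In monolayers at 2 h the other called lists depended on single libraries. NRF2 targets had a median of 0.37 and extracellular matrix genes −0.84 (camera adjusted p = 3.23e-06 and 0.000701, and adjusted p = 0.63 for both with an estimated correlation). Without replicate 1 before NEE, in which these lists stood apart, the medians were 0.01 and 0.09 (camera adjusted p = 0.995 and 0.989). G2/M genes had 0.20 (camera adjusted p = 0.00237, and adjusted p = 0.63 with an estimated correlation) and lost the call without replicate 2 before NEE (0.189). NF-kB targets had 0.43 (camera adjusted p = 0.00884, and adjusted p = 0.636 with an estimated correlation) and lost it without replicate 2 before NEE (0.459) or replicate 1 at 2 h (0.497). YAP/TAZ targets had 0.33 with 2 members called adjusted over the list alone (camera adjusted p = 0.0157, and adjusted p = 0.63 with an estimated correlation), and lost the call without replicate 1 (0.0645) or 2 (0.56) before NEE or replicate 1 at 2 h (0.103). The respiratory chain had −0.21 (camera adjusted p = 0.0371, and adjusted p = 0.67 with an estimated correlation) and lost it without replicate 2 before NEE (0.459) or replicate 1 (0.0541) or 2 (0.15) at 2 h.

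Right after NEE, no gene passed the test in either culture. In monolayers edgeR called 0 genes, with 401 at an unadjusted p under 0.05, and DESeq2 called 7, all lower. Without replicate 2 of the monolayers before NEE, edgeR called 36. The genes with the smallest p in monolayers included the leukocyte genes AOAH, a lipopolysaccharide hydrolase, at 0.439 ± 0.156 CPM against 14.8 ± 18.4 CPM before, and DOCK8, a regulator of immune cell migration, at 1.26 ± 0.313 against 15.7 ± 15.8 CPM (n = 2 each, edgeR adjusted p = 1 for both). Their log2 fold changes were −5.06 and −3.63, and −2.07 and −1.86 without replicate 1 of the monolayers before NEE. In spheroids edgeR called 0 genes, with 359 at an unadjusted p under 0.05, and DESeq2 called 1. The smallest p was that of COX10-DT, a long non-coding RNA beside COX10, at 21.5 ± 0.827 against 7.42 ± 1.25 CPM (log2 fold change 1.53, edgeR adjusted p = 1). Ribosomal protein genes were lower as a list in monolayers, with a median of −0.19 (camera adjusted p = 0.0074, and adjusted p = 0.934 with an estimated correlation), a call lost without replicate 2 before NEE (0.409) or replicate 1 right after (0.28). NRF2 targets had 0.28 and extracellular matrix genes −0.52 (camera adjusted p = 0.000704 and 0.00131, and adjusted p = 0.934 for both with an estimated correlation), and these became −0.18 and 0.07 without replicate 1 before NEE (0.513 and 0.726). In spheroids G1/S genes had −0.13 (camera adjusted p = 0.023, and adjusted p = 0.958 with an estimated correlation), a call lost without replicate 2 before NEE (0.644) or replicate 2 right after (0.987).

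At 24 h neither TIPARP nor CYP1B1 passed the test. TIPARP stood at log2 fold changes of −0.30 in monolayers and 0.45 in spheroids, and CYP1B1 at 0.84 and 0.97. In monolayers genes of the G2/M phase and mitosis were higher as a list, with all 21 members positive and a median of 0.51 (camera adjusted p = 2.09e-09, and adjusted p = 0.34 with an estimated correlation), 2 of them called adjusted over the list alone and 0 over all genes. Immediate early genes were lower, with 5 of 24 positive and a median of −0.87 (camera adjusted p = 9.85e-08, and adjusted p = 0.34 with an estimated correlation), 2 called adjusted over the list alone and 0 over all genes. In spheroids the respiratory chain was lower as a list, with a positive log2 fold change in 2 of 33 members, 0 called over all genes or adjusted over the list alone, and a median of −0.48 (camera adjusted p = 2.27e-13, and adjusted p = 0.231 with an estimated correlation). These 3 calls stood with each library left out, with a median of −1.46 for immediate early genes without replicate 1 of the 24 h monolayers. By edgeR 0 genes were called in monolayers and 0 in spheroids, with 788 and 445 at an unadjusted p under 0.05, and DESeq2 called 44 in monolayers (6 higher, 38 lower) and 0 in spheroids. Without replicate 2 before NEE edgeR called 92 genes in monolayers, and without replicate 1 of the 24 h spheroids 1 in spheroids.

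The remaining list calls at 24 h were each lost with at least 1 library left out. In monolayers NRF2 targets had a median of 0.59, extracellular matrix genes −1.03 and cytosolic protein mRNAs 0.30 (camera adjusted p = 4.99e-09, 1.22e-06 and 0.00152, and adjusted p = 0.34, 0.38 and 0.34 with an estimated correlation). Without replicate 1 before NEE these were 0.15, −0.30 and 0.12 (camera adjusted p = 0.164, 0.276 and 0.352), and without replicate 2 before NEE NRF2 targets had 1.26. YAP/TAZ targets had −0.37 (camera adjusted p = 0.00869, and adjusted p = 0.38 with an estimated correlation) and lost the call without replicate 1 (0.0646) or 2 (0.0652) before NEE or replicate 1 at 24 h (0.0549). Membrane and secreted protein mRNAs had −0.14 and heat shock genes 0.21 (camera adjusted p = 0.0295 and 0.037, and adjusted p = 0.371 and 0.38 with an estimated correlation). They lost the call without replicate 1 (0.0578 and 0.138) or 2 (0.284 and 0.182) before NEE or replicate 1 at 24 h (0.207 and 0.269). The 3 endothelial markers had −2.21, or 0 with genes of an empty group at their bounds (camera adjusted p = 0.0293, and adjusted p = 0.34 with an estimated correlation), a call lost without any 1 of the 4 libraries (0.0646 to 0.0952), with −3.11 without replicate 1 and 0.00 without replicate 2 before NEE. In spheroids the unfolded protein response had −0.42 (camera adjusted p = 0.00217, and adjusted p = 0.231 with an estimated correlation), lost without replicate 2 before NEE (0.0766) or replicate 1 at 24 h (0.477). Cholesterol genes had −0.20, NF-kB targets −0.71, hypoxia genes −0.33, ribosomal protein genes −0.20 and membrane and secreted protein mRNAs −0.17 (camera adjusted p = 0.00397, 0.00701, 0.0061, 0.00785 and 0.0409). With an estimated correlation the adjusted p of the last was 0.815 and of the other 4 it was 0.905. The NF-kB, hypoxia and ribosomal protein calls were lost without replicate 1 before NEE (0.476, 0.352 and 0.476) or replicate 2 at 24 h (0.669, 0.669 and 0.168). The NF-kB and hypoxia medians were 1.03 and 0.35 without replicate 1 before NEE, and that of NF-kB was −1.45 without replicate 1 at 24 h. The cholesterol call was lost without replicate 2 before NEE (0.851) or replicate 1 at 24 h (0.505), and that of membrane and secreted protein mRNAs without any 1 of the 4 libraries (0.0766 to 0.38).

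Whether spheroids and monolayers responded differently was tested by the interaction of culture and time. EdgeR called 0 genes right after NEE, 0 at 2 h and 0 at 24 h, with 516, 555 and 628 at an unadjusted p under 0.05, and DESeq2 called 1, 3 and 11. Without replicate 2 of the monolayers before NEE edgeR called 12, 2 and 6, and without replicate 1 of the 24 h spheroids 1 at 24 h. The smallest p at 2 h was that of FOSB (edgeR adjusted p = 1), and at 24 h that of MINAR1, a regulator of Notch signalling and angiogenesis (edgeR adjusted p = 1). ATP2A3, a calcium pump of the endoplasmic reticulum, had a log2 interaction of 3.26 at 2 h and 4.08 at 24 h without passing the test (edgeR adjusted p = 1 for both). The change of G2/M genes in spheroids minus that in monolayers had a median of −0.46 at 2 h and −0.39 at 24 h (camera adjusted p = 4.82e-06 and 0.000105, and adjusted p = 0.57 and 0.502 with an estimated correlation), calls that stood with each library left out. Across 8534 genes the log2 fold changes of the cultures had a Pearson r of −0.004 right after NEE, 0.215 at 2 h and 0.066 at 24 h, and −0.212, 0.181 and 0.053 without replicate 1 of the monolayers before NEE. Genes are not independent replicates, and no p is given for these.

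The culture forms were compared over all 4 times, with 8 spheroid and 8 monolayer libraries. These are 2 replicate numbers at each of the 4 times, and the fit takes the libraries as independent. CA9 and ALDOC were higher in spheroids. CA9, a carbonic anhydrase induced by low oxygen, stood at 230 ± 89.3 CPM in spheroids and 2.67 ± 3.17 CPM in monolayers (mean ± SD, n = 8 each), a log2 fold change of 6.91 ± 0.39 (SE, edgeR adjusted p = 9.98e-07). ALDOC, a glycolytic aldolase, stood at 256 ± 64.4 against 13.1 ± 4.33 CPM, a log2 fold change of 4.32 ± 0.18 (SE, edgeR adjusted p = 1.69e-08). DNA replication genes were lower, among them MCM10, a replication fork factor, at 46.7 ± 8.64 against 212 ± 20.1 CPM, a log2 fold change of −2.19 ± 0.12 (SE, edgeR adjusted p = 4.86e-07). CA9 (ENSG00000107159) lies on chromosome 9 at 35673856 to 35681159, ALDOC (ENSG00000109107) on chromosome 17 at 28573115 to 28577264 and MCM10 (ENSG00000065328) on chromosome 10 at 13161554 to 13211104 (GRCh38). EdgeR called 3542 of 17822 genes, 1788 higher and 1754 lower in spheroids, and 3523 of them had the same sign in both replicate numbers. The genes were called from these same libraries, which favours such agreement, so it is not separate support. Of the 3542 genes, 1595 differed by at least 2-fold, 972 higher and 623 lower.

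Among the largest rises in spheroids were those of CA9, the fibrinogen chains FGG (log2 fold change 4.35) and FGB (3.98), ALDOC and LCN2, the iron-sequestering protein lipocalin (4.02). SLC6A14, an amino acid transporter (5.15 against 0.0956 CPM), SLITRK6, a neural membrane protein (14.6 against 0.551 CPM), and SPTSSB, a subunit of serine palmitoyltransferase (11.9 against 0.775 CPM), were among them too, and since monolayer groups at some times lie near or below the floor no fold is given for these 3. The largest falls were those of TNC, the matrix protein tenascin (−3.10), POLR3G, an RNA polymerase subunit (−2.91), HPDL, a dioxygenase-like protein (−2.89), ZNF488, a zinc finger protein (−2.83), BCAT1, an amino acid transaminase (−2.65), THY1, a surface glycoprotein (−2.49), SLAMF7, an immune cell receptor (−2.19), and MCM10. Single libraries moved several of these values. LCN2 had 4.79 and 4.71 without replicate 2 of the 2 h and of the 24 h monolayers. TNC had −4.45 and −4.70 without replicate 1 of the spheroids before and 24 h after NEE, HPDL −4.32 without replicate 2 of the spheroids before NEE and THY1 −3.14 without replicate 1 of the 24 h spheroids. These 16 genes had edgeR adjusted p from 1.69e-08 for ALDOC to 0.0214 for TNC. The call of TNC was lost without replicate 2 of the spheroids right after NEE (edgeR adjusted p = 0.0582) or at 2 h (0.0557). GAPDH was higher by 0.84 and the nuclear RNA NEAT1 by 0.61 (edgeR adjusted p = 0.00257 and 0.00902). MALAT1, another nuclear RNA, at −0.33, was not called (edgeR adjusted p = 0.438), except without replicate 1 of the spheroids before NEE (0.0338). ACTB at −0.31 was not called either (edgeR adjusted p = 0.0715), except with the replicate block (0.0143) and without replicate 1 of the spheroids right after NEE (0.0418), at 2 h (0.0415) or at 24 h (0.0495).

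By list, 5 calls held both with the preset and with an estimated correlation, and with each library left out. G1/S and DNA replication genes were lower, 20 of 22 members called (21 adjusted over the list alone), with a median of −1.36 (camera adjusted p = 4.07e-36, and adjusted p = 0.00968 with an estimated correlation). They included CDC6, a loader of the replicative helicase, at −1.80, and the helicase subunit MCM6 at −1.49. G2/M genes were lower, 19 of 21 called (19 adjusted over the list alone), median −0.99 (camera adjusted p = 9.74e-20, and adjusted p = 0.0406 with an estimated correlation), such as CDC20, an activator of the anaphase-promoting complex, at −1.14. The heat shock response was lower, 10 of 17 called (12 adjusted over the list alone), median −0.59 (camera adjusted p = 1.8e-06, and adjusted p = 0.0406 with an estimated correlation), with the chaperone HSP90AA1 at −1.34. The unfolded protein response was higher, 13 of 17 called (13 adjusted over the list alone), median 0.71 (camera adjusted p = 4.38e-09, and adjusted p = 0.0121 with an estimated correlation), with its transcription factor XBP1 at 2.03. Membrane and secreted protein mRNAs were higher, 20 of 32 called higher and 1 lower (21 adjusted over the list alone), median 0.55 (camera adjusted p = 7.55e-09, and adjusted p = 0.0181 with an estimated correlation). The growth factor precursor GRN, at 1.36, and the lysosomal protease CTSD, at 1.55, belonged to these.

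The hypoxia and glycolysis list was higher, 17 of 28 called and none lower (21 adjusted over the list alone), median 1.16 (camera adjusted p = 7.06e-21, and adjusted p = 0.15 with an estimated correlation), with the glycolytic kinase PGK1 at 1.88. NRF2 targets were higher, 9 of 24 called higher and 1 lower (13 adjusted over the list alone), median 0.38 (camera adjusted p = 0.000421, and adjusted p = 0.464 with an estimated correlation). Ribosomal protein genes were lower, 15 of 76 called lower and 2 higher (21 adjusted over the list alone), median −0.34 (camera adjusted p = 0.00057, and adjusted p = 0.517 with an estimated correlation). YAP/TAZ targets were lower, 6 of 19 called (7 adjusted over the list alone), median −0.69 (camera adjusted p = 0.00936, and adjusted p = 0.443 with an estimated correlation). These 4 calls also stood with each library left out, and 5 others did not. NF-kB targets had 0.81, 5 of 21 called higher and 1 lower, actin cytoskeleton genes −0.35, 6 of 22 called lower, and immediate early genes −0.46, 6 of 24 called lower (camera adjusted p = 0.0173, 0.0216 and 0.0231, and adjusted p = 0.517, 0.509 and 0.514 with an estimated correlation). ATF4 targets had −0.37, 6 of 20 called lower and 2 higher, and p53 targets −0.17, 7 of 21 called lower (camera adjusted p = 0.0231 and 0.0381, and adjusted p = 0.444 and 0.464 with an estimated correlation). Adjusted over the list alone, 8, 8, 7, 10 and 8 members of these 5 lists were called. The NF-kB call was lost without replicate 2 of the monolayers before NEE (0.0662) or replicate 1 of the spheroids before (0.0736), right after (0.0994) or 24 h after NEE (0.0531). The actin call was lost without replicate 2 of the monolayers right after NEE (0.0516), the 2 h spheroids (0.0616) or the 24 h spheroids (0.0793). The immediate early call was lost without replicate 2 of the same libraries (0.0591, 0.0736 and 0.0793) or replicate 1 of the 24 h monolayers (0.0617). The ATF4 call was lost without replicate 1 of the 2 h monolayers (0.0506) or replicate 2 of the spheroids right after (0.059) or 2 h after NEE (0.0616). The p53 call was lost without replicate 2 of any monolayer group (0.0677 to 0.112), without replicate 1 of the spheroids right after NEE (0.0549) or without replicate 2 of the 2 h (0.0674) or 24 h spheroids (0.0723).

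**Figure D3:**
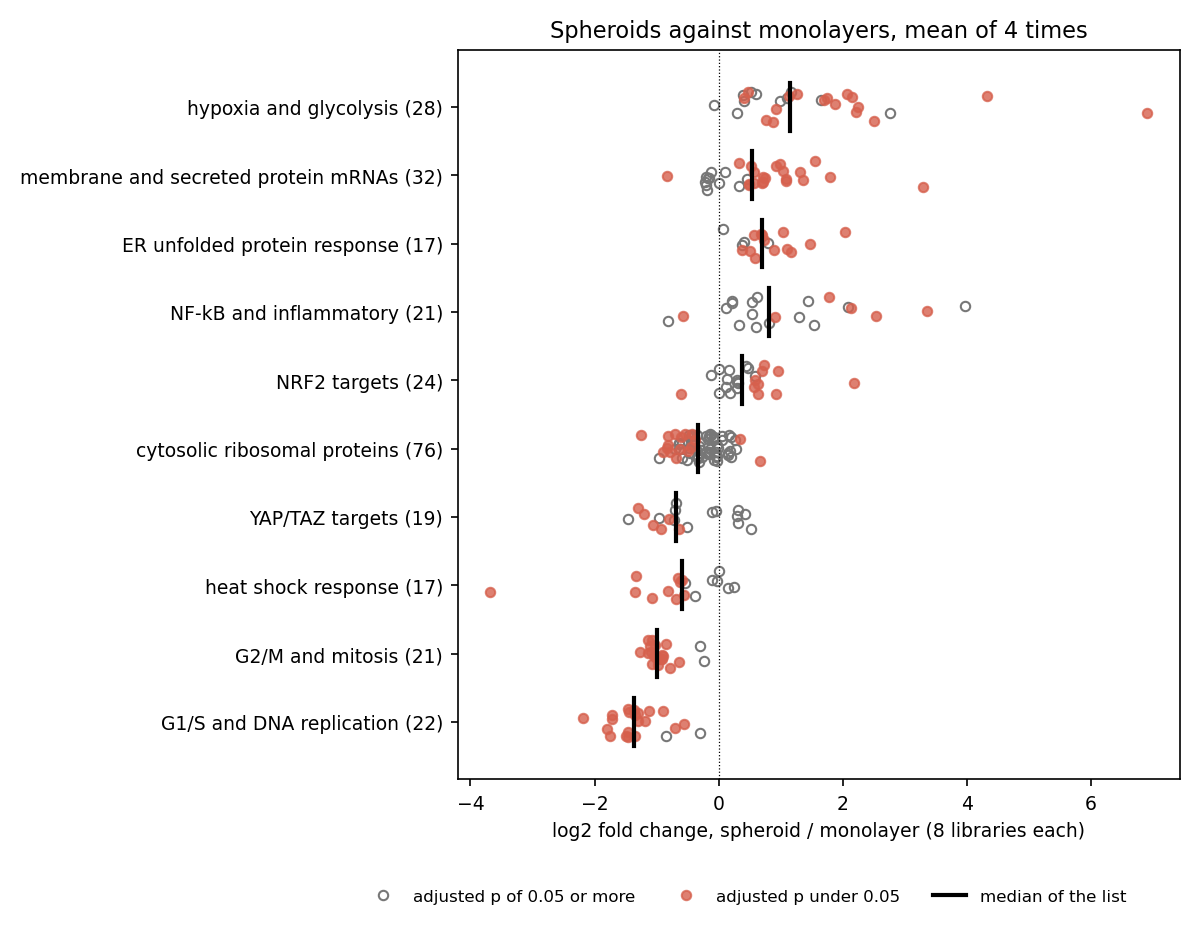
Log2 fold change of spheroids over monolayers, mean of the 4 times, for the members of 10 gene lists (number tested in brackets). Each point is a gene, filled where its adjusted p is under 0.05, and bars mark list medians, which run from 1.16 for hypoxia and glycolysis to −1.36 for G1/S and DNA replication.

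The other lists did not pass the test over all 4 times. Interferon-stimulated genes had a median of 0.61, extracellular matrix genes −0.47 and the respiratory chain −0.19 (camera adjusted p = 0.0926 for each). With the replicate block the extracellular matrix list was called lower (camera adjusted p = 0.023) and the epithelial list, at a median of 0.07, higher (0.0177 against 0.184 without the block). Cholesterol synthesis genes had 0.19, nuclear-retained RNAs −0.22, alveolar markers 0.58 and fibroblast markers −1.15 (camera adjusted p = 0.0753, 0.151, 0.162 and 0.184). Leukocyte and red cell markers had 1.03 (camera adjusted p = 0.184), and were called higher in spheroids without replicate 1 of the monolayers before NEE (0.0144). Of the 8 leukocyte and red cell markers tested, 2 were called higher, CD14 (log2 fold change 2.22) and CD79A, at 0.656 CPM in spheroids and 0.181 CPM in monolayers, near the floor, with single libraries overlapping (0.325 to 1.23 and 0 to 1.08 CPM), so no fold is given. The call of CD79A was lost with the replicate block within culture (edgeR adjusted p = 0.21) and without replicate 1 of the monolayers right after NEE (0.0506). CD14 had 3.07 without replicate 2 of the monolayers before NEE. Metallothionein and zinc genes had −0.40, endothelial markers 0.61, membrane repair genes −0.15 and cytosolic protein mRNAs −0.02 with a mean of 0.01 (camera adjusted p = 0.668, 0.77, 0.986 and 0.986).

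Before NEE alone, with 2 libraries of each culture, fewer genes were called. ALDOC stood at 283 ± 96.1 CPM in spheroids and 9.82 ± 2.82 CPM in monolayers (mean ± SD, n = 2 each), a log2 fold change of 4.85 ± 0.36 (SE, edgeR adjusted p = 4.82e-05). PGK1 was higher by 2.26, and MCM10 was at 46.3 ± 0.667 against 223 ± 18.5 CPM, a log2 fold change of −2.27 ± 0.24 (edgeR adjusted p = 0.00217 and 0.00213). CDC6 at −1.84, GRN at 1.53, CTSD at 2.01 and JUP, a junction protein, at 1.88 were also called in the full fit with each library left out (edgeR adjusted p = 0.00273, 0.00217, 0.00371 and 0.00402). CA9 had 6.79 ± 0.76 (edgeR adjusted p = 0.00217), lost without replicate 1 of the monolayers (0.0549), and 6.02 without replicate 1 of the spheroids. EdgeR called 231 genes, 125 higher and 106 lower in spheroids, and with the replicate block 612. A fit of these 4 libraries alone called 0 by edgeR, so none of the genes named here was called in it, while 2925 genes were at an unadjusted p under 0.05 in the full fit and DESeq2 called 1351. The count was 34 without replicate 1 of the monolayers, 1218 without replicate 2, 39 without replicate 1 of the spheroids and 64 without replicate 2. Among genes called lower, CORO1A, a leukocyte actin regulator, stood at 5.54 ± 0.435 against 64.3 ± 71.3 CPM and was not called without replicate 1 of the monolayers (edgeR adjusted p = 0.034 with it and 0.34 without it).

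Of the lists before NEE, the unfolded protein response was higher with either correlation, median 0.84 (camera adjusted p = 4.97e-07, and adjusted p = 0.0478 with an estimated correlation), with 2 of 17 called and 8 adjusted over the list alone. Hypoxia and glycolysis genes were higher as a list, with a positive log2 fold change in all 28 members and a median of 1.49 (camera adjusted p = 2.47e-19, and adjusted p = 0.225 with an estimated correlation), with 5 called and 16 adjusted over the list alone. G1/S genes were lower, median −1.12 (camera adjusted p = 6.84e-19, and adjusted p = 0.0621 with an estimated correlation), with 9 of 22 called and 16 adjusted over the list alone. NRF2 targets had 0.80 and membrane and secreted protein mRNAs 0.47 (camera adjusted p = 6.37e-08 and 1.09e-05, and adjusted p = 0.308 and 0.068 with an estimated correlation). G2/M genes had −0.72, YAP/TAZ targets −0.94 and immediate early genes −0.96 (camera adjusted p = 1.01e-05, 0.000485 and 0.00153, and adjusted p = 0.371, 0.27 and 0.39 with an estimated correlation). The hypoxia median was 0.70 without replicate 1 of the spheroids, and that of NRF2 targets 1.41 without replicate 2 of the monolayers. These 8 calls stood with each library left out, and the other 8 of the 16 did not. Extracellular matrix genes, at −1.25 (camera adjusted p = 0.000489, and adjusted p = 0.39 with an estimated correlation), lost the call without replicate 1 of the monolayers (0.187, median −0.66) or replicate 2 of the spheroids (0.0862). Heat shock genes had −0.46 and ATF4 targets −0.49 (camera adjusted p = 0.00252 and 0.0274, and adjusted p = 0.231 and 0.389 with an estimated correlation). Both lost the call without replicate 2 of the monolayers (0.0507 for both) or replicate 1 of the spheroids (0.0612 for both), and ATF4 targets also without replicate 2 of the spheroids (0.0992). NF-kB targets had 1.26 and cholesterol synthesis genes 0.36 (camera adjusted p = 0.0126 for both, and adjusted p = 0.507 for both with an estimated correlation). They lost the call without replicate 2 of the monolayers (0.186 and 0.161), and NF-kB targets also without replicate 1 of the spheroids (0.975, median 0.00) and cholesterol genes without replicate 2 (0.55). Ribosomal protein genes had −0.34 and nuclear-retained RNAs −0.56 (camera adjusted p = 0.00252 and 0.0247, and adjusted p = 0.567 and 0.389 with an estimated correlation). Both lost the call without replicate 2 of the monolayers (0.0953 for both), and nuclear-retained RNAs also without replicate 2 of the spheroids (0.555), with a median of −1.34 without replicate 1 of the spheroids. Actin genes had −0.43, or −0.34 with a gene at its bound (camera adjusted p = 0.0178, and adjusted p = 0.459 with an estimated correlation), lost without replicate 2 of the spheroids (0.0786). Epithelial genes were called only with the replicate block (camera adjusted p = 0.121 without and 0.0085 with it). Leukocyte and red cell markers and p53 targets were called only without replicate 1 of the monolayers (camera adjusted p = 0.628 and 0.0674 with it, and 0.00385 and 0.0025 without it).

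NEE-sampled RNA was sequenced in 3 technical replicates to measure its reproducibility. Across genes, the replicates had a mean Pearson r of 0.945 of log2(CPM + 1), with pairs from 0.943 to 0.948, and a mean Spearman rho of 0.94. Over genes found in either library of a pair, the basis used for lysates, NEE pairs had r from 0.937 to 0.942. Pairs of lysate replicates, which are biological and not technical, had r from 0.915 to 0.964. The lowest was that of monolayers before NEE, with the library set apart, and the next was 0.937 in spheroids before NEE. Of 14093 genes at 1 CPM or more in any of the 3 libraries, 10990 were so in all (78.0%). By pairs of NEE libraries, which compare in number with the 2 libraries of a lysate group, 84.4 to 85% of genes were shared, against 84.7 to 88.3% in the lysate groups. The lowest lysate share was again that of monolayers before NEE. The next was 85.8% in the 24 h spheroids, above every NEE pair. The median coefficient of variation between the 3 libraries was 48.2% for genes at 1 to 10 CPM, 21.5% at 10 to 100 CPM, 12.6% at 100 to 1000 CPM and 11.3% above, where counting alone gives 13.3%, 4.81%, 1.87% and 0.591%. The NEE libraries held 16397 to 16583 genes with a count, against 18433 to 22115 in lysates, and their 50 most abundant genes took 32.1 to 34.5% of the counts, against 16 to 22.8%.

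The lysate transcriptome was covered in step with abundance. Of 13415 genes at 1 CPM or more in the monolayer lysate before NEE, 10623 (79.2%) were at 1 CPM or more in all 3 NEE libraries and 91.5% in any. The share in all 3 was 50.3% for lysate genes at 1 to 10 CPM, 93.5% at 10 to 100 CPM, 99.6% at 100 to 1000 CPM and 100% above. The 2 genes above 100 CPM in lysate that no NEE library reached, LCP1, a leukocyte plastin (132 against 0.0955 CPM), and PRF1 (105 against 0.168 CPM), are leukocyte genes raised in replicate 1 of that lysate. Mean log2(CPM + 1) of NEE-sampled RNA had a Pearson r of 0.822 across genes with monolayers before NEE, and 0.834 to 0.861 with the other lysate groups, the highest being spheroids right after NEE. Without replicate 1 of the monolayers before NEE the r was 0.859, and without replicate 2 it was 0.762. Lysate groups of one culture had r of 0.977 to 0.986 and lysate groups of different cultures 0.944 to 0.966.

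NEE-sampled RNA differed from monolayer lysate before NEE in the kinds of transcript it held. The ferritin genes, iron storage proteins, were higher. FTL stood at 131000 ± 25200 CPM in NEE-sampled RNA and 6370 ± 3030 CPM in lysate (mean ± SD, n = 3 technical and 2 biological), a log2 fold change of 4.36 ± 0.33 (SE, edgeR adjusted p = 1.57e-05), and 4.95 without replicate 2 of the lysates. FTH1 stood at 5960 ± 980 against 252 ± 87.7 CPM, 4.56 ± 0.28 (SE, edgeR adjusted p = 5.45e-06). Both have many processed pseudogenes, and the handling of reads shared with them is not given, so their levels are uncertain. FTL took 9.68 to 13.3% of the counts in NEE-sampled libraries and 0.478 to 1.61% in lysates, and the ferritin pseudogenes took 0.0283 to 0.0405% in the former and 0.00149 to 0.00291% in the latter. ITGB1, an integrin that anchors cells to matrix, was lower, at 161 ± 19.9 against 2810 ± 1020 CPM, a log2 fold change of −4.13 ± 0.25 (SE, edgeR adjusted p = 5.45e-06). The nuclear RNA NEAT1 was at 13.7 ± 4.49 against 124 ± 7.44 CPM, −3.18 ± 0.30 (SE, edgeR adjusted p = 3.58e-05). FTL (ENSG00000087086) lies on chromosome 19 at 48965301 to 48966878, FTH1 (ENSG00000167996) on chromosome 11 at 61959718 to 61967660, ITGB1 (ENSG00000150093) on chromosome 10 at 32900319 to 33005792 and NEAT1 (ENSG00000245532) on chromosome 11 at 65422774 to 65445540 (GRCh38).

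EdgeR called 6493 of 17067 genes, 2660 higher and 3833 lower in NEE-sampled RNA, and 3943 without replicate 1 of the monolayers before NEE (1505 higher, 2438 lower). The median log2 fold change of all genes was −0.213 with TMM scaling and −0.083 with upper-quartile scaling, a shift of 0.131. The extraction kit, the amount of RNA and the way of sampling all differ between these groups, and the spread of the NEE libraries is technical. The 3 NEE libraries are repeats and not independent samples, and the fit takes each as a replicate. With them summed into 1 library edgeR called 3993 genes, 1738 higher and 2255 lower. Among the largest rises, C2orf72 was at least 338-fold, GSTA2, a glutathione transferase, at least 100-fold and KRTAP4-1, a keratin-associated protein, at least 84.5-fold higher against a floor of 3 counts over the lysate group. CA9 had a log2 fold change of 6.44, and 5.64 without replicate 3 of the NEE libraries. EPS8L3 (12.5 against 0.036 CPM), CST1, a cystatin (7.67 against 0.085 CPM), ANKS4B (11.1 against 0.17 CPM) and ABHD17A, a depalmitoylase (6.44 against 0.09 CPM), completed these, and since their lysate levels lie near or below the floor no fold is given. GSTA2 and ABHD17A lost the call without replicate 1 of the lysates (edgeR adjusted p = 0.0504 and 0.051), and ABHD17A also without replicate 2 (0.102) and with the NEE libraries summed (0.0868). Among the largest falls, CCND2, a cyclin, was at least 368-fold, CRISPLD1 at least 289-fold, BMPER, a BMP-binding protein, at least 202-fold and CRISPLD2 at least 189-fold lower, with no count in the 3 NEE libraries. CCND2 stood at 54.9 CPM in replicate 1 of the lysates and 1.52 CPM in replicate 2, and BMPER at 26.5 and 4.51 CPM, so their bounds rest mostly on replicate 1. CRISPLD2 stood at 9.11 and 19.9 CPM. The leukocyte genes CD53 (at least 278-fold), HCLS1 (at least 189-fold), AOAH (at least 182-fold) and SELPLG (at least 172-fold) were among these falls too, and their lysate means rest mostly on replicate 1, with 41.4 and 1.27 CPM in replicates 1 and 2 for CD53, 28.1 and 0.882 CPM for HCLS1, 26.1 and 1.81 CPM for AOAH and 24.3 and 2.06 CPM for SELPLG. Without replicate 1 of the lysates all 8 genes were still lower in NEE-sampled RNA. In replicate 2 the levels of CCND2 and of the leukocyte genes are low and may include reads exchanged from replicate 1. For these genes the fall without replicate 1 is therefore not independent support.

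Among the lists, 70 of 76 ribosomal protein genes were higher in NEE-sampled RNA and none lower (72 adjusted over the list alone), with a median of 2.27 (camera adjusted p = 1.58e-44, and adjusted p = 0.107 with an estimated correlation). RPL12 was at 3.60, and the list took 6.23 to 7.62% of the counts against 1.27 to 1.82% in lysates. Many ribosomal protein genes have near-identical pseudogenes, so single levels are uncertain. Nuclear-encoded respiratory chain subunits were higher, 29 of 33 called (29 adjusted over the list alone), median 1.46 (camera adjusted p = 3.46e-13, and adjusted p = 0.213 with an estimated correlation), with NDUFB10 at 2.32. Cytosolic protein mRNAs were higher, 18 of 23 called higher and 1 lower (19 adjusted over the list alone), median 1.73 (camera adjusted p = 3.58e-11, and adjusted p = 0.107 with an estimated correlation), with the translationally controlled protein TPT1 at 3.15 and GAPDH at 2.40, or 3.22 without replicate 2 of the lysates. NRF2 targets were higher, 15 of 24 called higher and 4 lower (20 adjusted over the list alone), median 1.15 (camera adjusted p = 2.39e-05, and adjusted p = 0.344 with an estimated correlation). Besides the ferritins they included AKR1C1, an aldo-keto reductase, at 2.87, with 2.27 without replicate 1 and 3.91 without replicate 2 of the lysates.

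Extracellular matrix and mesenchymal genes were lower, 22 of 25 called (23 adjusted over the list alone), median −3.92, −2.80 without replicate 1 of the lysates and −3.31 without replicate 3 of the NEE libraries (camera adjusted p = 2.46e-09, and adjusted p = 0.169 with an estimated correlation). Membrane and secreted protein mRNAs were lower, 21 of 32 called lower and 3 higher (24 adjusted over the list alone), median −1.74 (camera adjusted p = 1.7e-07, and adjusted p = 0.163 with an estimated correlation), with the lysosomal precursor PSAP at −3.13. Nuclear-retained long RNAs were lower, 7 of 10 called (8 adjusted over the list alone), median −2.17 (camera adjusted p = 5.79e-05, and adjusted p = 0.0974 with an estimated correlation), with the imprinted RNA MEG3 at 0.163 against 86.3 CPM, near the floor in NEE-sampled RNA. MALAT1 was at −1.32 (edgeR adjusted p = 0.0266), a call lost with the replicate block (0.0982), without replicate 1 (0.0559) or 2 (0.104) of the lysates without replicate 2 (0.0797) or 3 (0.0793) of the NEE libraries and with the NEE libraries summed (0.113). YAP/TAZ targets were lower, 11 of 19 called (11 adjusted over the list alone), median −2.0 (camera adjusted p = 0.000884, and adjusted p = 0.0974 with an estimated correlation). G1/S genes were lower, 14 of 22 called lower and 4 higher (19 adjusted over the list alone), median −1.26 (camera adjusted p = 0.000887, and adjusted p = 0.213 with an estimated correlation). Immediate early genes were lower, 13 of 25 called lower and 2 higher (16 adjusted over the list alone), median −1.98, or −1.91 with 3 genes at their bounds and −1.38 without replicate 1 of the lysates (camera adjusted p = 0.00335, and adjusted p = 0.344 with an estimated correlation). G2/M genes were lower, 10 of 21 called lower and 2 higher (14 adjusted over the list alone), median −0.77 (camera adjusted p = 0.0163, and adjusted p = 0.557 with an estimated correlation), a call lost with the replicate block (0.0658). The unfolded protein response was lower, 8 of 17 called lower and 3 higher (11 adjusted over the list alone), median −0.64 (camera adjusted p = 0.0425, and adjusted p = 0.405 with an estimated correlation), with the chaperone HSPA5 at −3.50. This call was lost without replicate 2 of the lysates (0.0665), without replicate 1 (0.089) or 2 (0.14) of the NEE libraries with RLE scaling (0.0527) and with the NEE libraries summed (0.135).

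**Figure D4:**
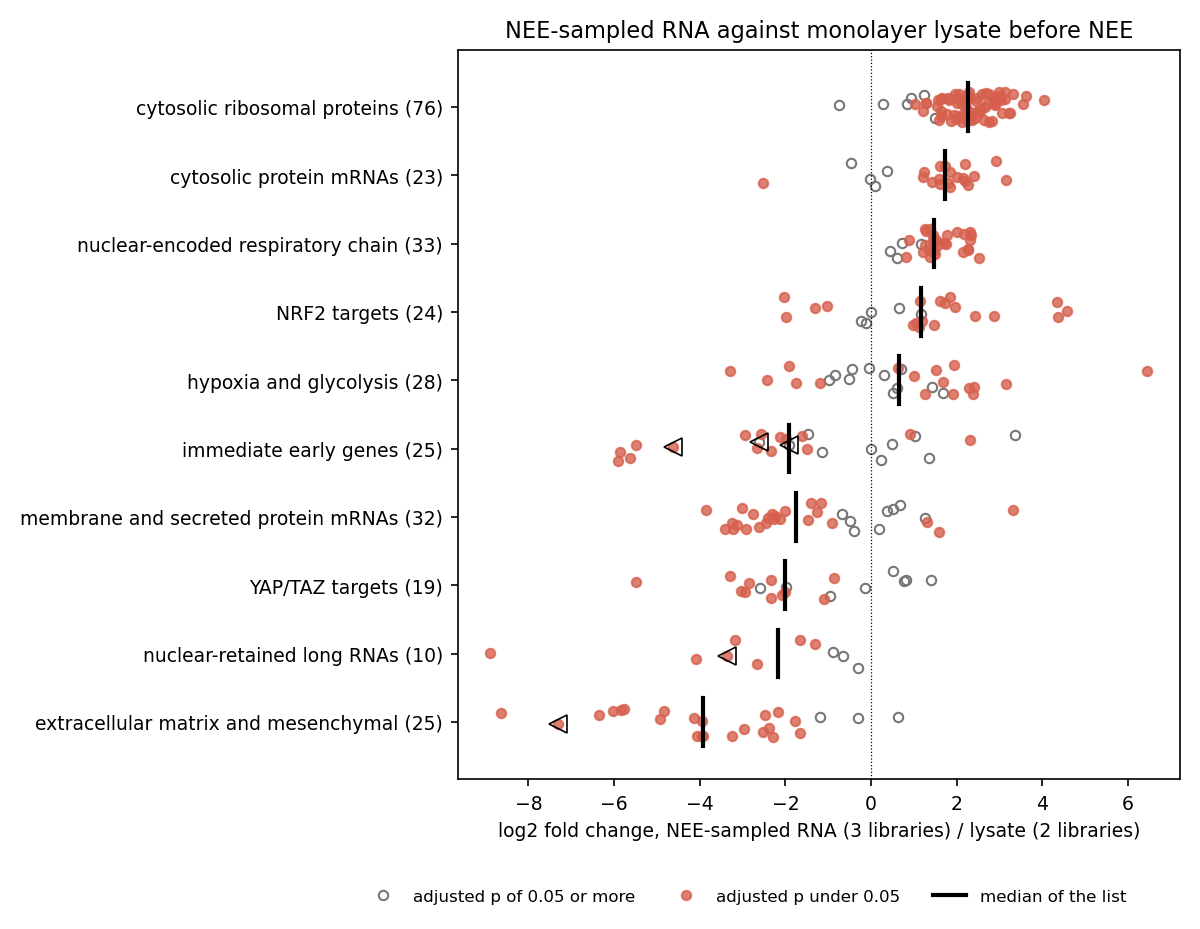
Log2 fold change of NEE-sampled RNA (3 libraries) over monolayer lysate before NEE (2 libraries) for the members of 10 gene lists (number tested in brackets). Each point is a gene, filled where its adjusted p is under 0.05, triangles mark genes with no count in a group placed at their bound, and bars mark list medians, from 2.27 for ribosomal proteins to −3.92 for extracellular matrix.

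The other lists did not pass the test between NEE-sampled RNA and lysate. The hypoxia and glycolysis list had a median of 0.66, with 12 of 28 members called higher and 5 lower (camera adjusted p = 0.0594), and was called without replicate 1 of the lysates (0.0119). Cholesterol synthesis genes had −0.19, NF-kB targets −1.15 and ATF4 targets −0.52 (camera adjusted p = 0.104, 0.116 and 0.196). Single members of these lists were called, among them the amino acid transporter subunit SLC3A2 at −2.64. Actin cytoskeleton genes had −0.48, or −0.24 with a gene at its bound, and heat shock genes −0.25 (camera adjusted p = 0.634 and 0.792), with the focal adhesion protein VCL at −4.39 (−3.71 without replicate 1 of the lysates) and the small heat shock protein HSPB1 at 3.09. Fibroblast markers had −1.56, leukocyte and red cell markers −4.70, interferon-stimulated genes −0.78 and alveolar markers 0.35 (camera adjusted p = 0.615, 0.792, 0.934 and 0.694). The leukocyte and red cell median rests on replicate 1 of the lysates and was 0.36 without it. For membrane repair genes the median of 0.40 and the mean of −0.12 differed in sign, as they did for p53 targets (0.05 and −0.23), epithelial genes (0.11 and −0.62) and metallothionein and zinc genes (0.08 and −0.07). The test pointed up for membrane repair and metallothionein genes and down for the other 2 (camera adjusted p = 0.531, 0.934, 0.832 and 0.832). ACTB, at 0.39, was not called (edgeR adjusted p = 0.109), except with upper-quartile scaling (0.044) or a stricter filter (0.0404).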

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

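Tests chosen only after the result was seen were those of natural killer and T cell RNA in replicate 1 of the monolayers before NEE and, for the rise at 2 h, those of single libraries, of scaling and of the aryl hydrocarbon receptor. The label rule of the test of dilution was also changed after its result was seen.

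The change after NEE differed between spheroids and monolayers in 24 of 81 tests of gene lists, by camera on the interaction with the preset correlation. With an estimated correlation 0 of the 24 were called, with lowest camera adjusted p of 0.936, 0.57 and 0.502 at the 3 times. Each value is the median log2 change in spheroids minus that in monolayers. Right after NEE it was −0.30 for G1/S genes, −0.34 for NRF2 targets, −0.26 for G2/M genes, 0.23 for ribosomal protein genes and 0.68 for extracellular matrix genes (camera adjusted p = 0.0154 for each). At 2 h it was −0.46 for G2/M genes, 0.86 for extracellular matrix genes, −0.31 for NRF2 targets and −0.39 for hypoxia genes (camera adjusted p = 4.82e-06, 0.000424, 0.000484 and 0.000484). It was 0.62 for immediate early genes, −0.32 for G1/S genes, −0.24 for the respiratory chain and 0.67 for YAP/TAZ targets (camera adjusted p = 0.00854, 0.0101, 0.0139 and 0.0281). At 24 h it was −0.62 for NRF2 targets, 1.11 for extracellular matrix genes, −0.44 for the respiratory chain and −0.39 for G2/M genes (camera adjusted p = 2.44e-07, 4.73e-05, 0.000105 and 0.000105). It was 0.87 for immediate early genes, −0.38 for hypoxia genes, 0.63 for YAP/TAZ targets and −0.36 for cholesterol genes (camera adjusted p = 0.00062, 0.00146, 0.00913 and 0.013). It was −0.27 for the unfolded protein response, 0.43 for nuclear-retained RNAs and 3.38 for 3 endothelial markers near or below the floor (camera adjusted p = 0.0199, 0.0307 and 0.0307). Without replicate 1 of the monolayers before NEE 11 of the 24 were called, and with every library left out in turn only the G2/M genes at 2 h and at 24 h were. Single libraries also moved the medians. For extracellular matrix genes right after NEE it was −0.07 without replicate 1 of the monolayers before NEE, 1.61 without replicate 1 of the spheroids before NEE, and −0.01 and 1.32 without replicates 1 and 2 of the spheroids right after NEE. At 2 h it was 1.89 for them without replicate 1 of the spheroids before NEE, and 0.12 and 1.52 without replicates 1 and 2 of the 2 h spheroids. Leaving out replicate 1 of the 2 h spheroids gave −0.34 for immediate early genes and 0.03 for YAP/TAZ targets, and leaving out replicate 2 of the monolayers before NEE −1.02 for NRF2 targets at 2 h and −1.23 at 24 h. For extracellular matrix genes at 24 h it was 0.48 without replicate 1 of the monolayers before NEE, 1.99 without replicate 1 of the spheroids before NEE and 0.26 without replicate 1 of the 24 h spheroids. Leaving out the latter gave 0.28 for immediate early genes and −1.17 for hypoxia genes at 24 h, and leaving out replicate 1 of the spheroids before NEE 0.23 for hypoxia genes and 1.05 for nuclear-retained RNAs. For the endothelial markers it was 1.58 and 4.15 without replicates 1 and 2 of the monolayers before NEE and 2.22 without replicate 2 of the 24 h spheroids. Of the 5 calls right after NEE, 3 were lost without replicate 1 of the monolayers before NEE, 2 without replicate 2, 4 and 2 without replicates 1 and 2 of the monolayers right after NEE, 5 without replicate 2 of the spheroids before NEE, and 2 and 3 without replicates 1 and 2 of the spheroids right after NEE (camera adjusted p = 0.0558 to 0.968). Of the 8 at 2 h, 6 and 1 were lost without replicates 1 and 2 of the monolayers before NEE, 1 and 3 without those of the 2 h monolayers, 3 and 5 without those of the spheroids before NEE and 5 and 2 without those of the 2 h spheroids (camera adjusted p = 0.0513 to 0.971). Of the 11 at 24 h, in the same order, 4 and 5, 4 and 3, 2 and 5, and 6 and 2 were lost (camera adjusted p = 0.0567 to 0.993). At an unadjusted p under 0.05 edgeR had 516, 555 and 628 genes in the interaction and called 0 at each time, and DESeq2 called 1, 3 and 11.

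Replicate 1 of the monolayers before NEE held leukocyte transcripts. A list of natural killer and T cell genes had a median log2 ratio of 4.39 (95% interval 3.77 to 4.52) against the other lysate libraries, with 29 of 30 genes highest in this library, while B cell (−0.09) and monocyte (−0.31) lists did not rise. CDKN2A, a gene that A549 cells have lost, had 18 counts in it, or 0.733 CPM (exact Poisson interval 0.434 to 1.16), against at most 0.103 CPM in the other lysate libraries. Both values are consistent with RNA of natural killer and T cells in that library, by a route that the files do not show. Over the members tested in the lysate fit, the median of NRF2 targets minus that of epithelial genes was −0.39 (95% interval −1.31 to 1.37). This interval holds 0 as dilution of the A549 RNA requires but is too wide to decide, and no biological explanation was tested.

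The rise of immediate early genes, TIPARP and CYP1B1 at 2 h was weighed over 26 genes. With RLE and upper-quartile scaling the lowest median was 0.97 (95% interval 0.48 to 1.5). Upper-quartile scaling moved the median of all genes at 2 h by only −0.02 in monolayers and −0.018 in spheroids. The choice among these scalings could thus not have removed the rise, and scaling in general is not tested by it. The intervals given here are drawn over genes and not over libraries, and the genes include TIPARP and CYP1B1, seen to rise beforehand. Whether one library or one replicate number carries it stays open, since the lowest of the 4 medians within a culture and a number was 0.56 (95% interval 0 to 1.37). Activation of the aryl hydrocarbon receptor may contribute, since 10 other known target genes, 8 of them tested, had medians of 0.74 in monolayers and 0.70 in spheroids, with a positive change in 7 of 8 in each, and 4 of them are also on other lists used here. Handling, medium and time in culture were not separated from NEE by any group, so a response to NEE and a response to handling stay open.

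The makeup of NEE-sampled RNA, with ribosomal protein, respiratory chain and cytosolic protein mRNAs higher and nuclear, matrix, membrane and secreted protein RNAs lower, was weighed against technical causes. After the trend over transcript length and GC content was removed, 6 of the 6 lists kept their sign beyond random lists. This argues against that trend as the whole cause. The interval of the nuclear-retained list after removal, −4.04 to 0.53, held 0. Length was that of the longest annotated transcript, with a median of 1842 bases for ribosomal protein genes. An effect of the length of the transcripts present therefore stays open. Thinning kept at least 98.7% of each median but hardly moves ratios, so depth stays open. Less sampling of RNA bound to the endoplasmic reticulum may contribute, with membrane and secreted protein mRNAs at −2.94 (95% interval −3.47 to −1.9) against cytosolic protein mRNAs after that removal. The kit, the amount of RNA and the sampling differ together between these groups, so this cannot be told apart from them. The cultures may differ too.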

How the results depend on the processing

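All alternatives reported here were planned except the sum of the NEE technical replicates, chosen after the result was seen, and the cause of each change was not tested except where fewer libraries or genes enter by construction.

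With the 3 NEE technical replicates summed into 1 library, 3993 genes differed from lysate in place of 6493, and 11 of 12 list calls were kept. Without the low-count filter edgeR called 52, 99 and 132 genes in monolayers and 1, 56 and 16 in spheroids right after, 2 h and 24 h after NEE. The interactions then had 25, 35 and 69, and the cultures before NEE 1193. The cultures before NEE had 424 with the stricter filter, 612 with the replicate block, 798 with the block within culture and 0 in a fit without the other groups, where 2925 genes in the full fit had an unadjusted p under 0.05. In monolayers at 2 h the block within culture and the fit without the other groups each left 0 by edgeR (605 in the full fit at an unadjusted p under 0.05), and in spheroids the block within culture gave 5. DESeq2 called 7, 53 and 44 in monolayers, 1 and 39 in spheroids right after and at 2 h, 1, 3 and 11 in the interactions and 1351 between the cultures before NEE, with 6 higher genes shared by the cultures at 2 h. A minimum of 2-fold left 1595 of the 3542 genes between the cultures over the 4 times. The mean Pearson r of NEE replicates was 0.882 with a pseudocount of 0.1 and 0.934 at 5 CPM, and the share of genes in all 3 was 80.1% at 5 CPM and 75.7% at 10 counts. The r with monolayer lysate was 0.711 at 5 CPM, and the share of lysate genes in all NEE libraries was 76.9% at 5 CPM and 81.9% at 10 counts.

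With each library left out in turn, edgeR called 0 to 36, 0 to 44 and 0 to 92 genes in monolayers and 0 to 0, 1 to 8 and 0 to 1 in spheroids at the 3 times. The interactions had 0 to 12, 0 to 2 and 0 to 6, the highest each time without replicate 2 of the monolayers before NEE, as were those of the monolayers. The cultures before NEE had 34 to 1218, the cultures over the 4 times 2518 to 4152, and NEE-sampled RNA 3943 to 6368. The r of NEE replicates was 0.937 to 0.942 and the share of genes in all 84.4 to 85%, since pairs replace 3 libraries. The r with lysate was 0.762 to 0.859 and the share of lysate genes 78.6 to 81.7%.

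Called lists reversed in the direction of the test as follows, each with the range of medians over the libraries left out. Without replicate 1 of the monolayers before NEE, NRF2 targets had −0.18 (to 0.75) and extracellular matrix genes 0.07 (from −1.10) in monolayers right after NEE, extracellular matrix genes 0.09 (from −1.30) at 2 h, and the interaction right after NEE was 0.09 (from −0.81) for NRF2 targets and −0.07 (to 1.61) for extracellular matrix genes. Without replicate 1 of the spheroids before NEE, hypoxia genes had 0.15 (from −0.90) at 2 h and 0.35 (from −0.86) at 24 h in spheroids and 0.23 (from −1.17) in the interaction at 24 h, and NF-kB targets 1.03 (from −1.45) at 24 h. Without replicate 2 of the 24 h spheroids, hypoxia genes and ribosomal protein genes (from −0.56) each had 0.08. Without replicate 1 of the 24 h spheroids, cholesterol genes had 0.13 (from −0.77), and −0.04 in the interaction (range −0.78 to −0.01). Without replicate 1 of the 2 h spheroids, the interaction was −0.34 (to 1.18) for immediate early genes and 0.03 (to 1.02) for YAP/TAZ targets. With the block within culture, cholesterol genes before NEE had 0.06, with the test pointing down.

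Of 1421 comparisons of a list call with an alternative, 1129 kept direction and call, 276 kept the direction and lost the call, and 16 reversed. The estimated correlation ended 95 of 101 calls. Of 5668 comparisons of a named gene, 5334 kept direction and side of the threshold, 264 lost the call and 70 gained it. The overall replicate block changed no other call that the report names than those given there. The block within culture ended 9 of 89 list calls and reversed 1. In 227 comparisons of named genes it ended 23 calls and added 3. Only some of these are given by name. Depth limits genes near 0.122 to 0.22 CPM, where 3 counts lie.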

Other observations

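The test of hypoxia genes in NEE-sampled RNA was chosen after the result was seen, and the test of other splits was planned.

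Splits that exchange the culture labels of libraries within each time were set beside the difference between spheroids and monolayers over the 4 times. Of 30 splits drawn from 648, 1 gave as many called genes as the real split, the real one itself with 3542, and the highest of the others gave 0 by edgeR. The number drawn was held to 30 by the run time. With the numbers taken to pair the samples, the 127 other splits that part the 2 libraries of every number and time are the fitting comparison. Only 21 of these were run, 6 drawn and 15 chosen, with a median of 0 and a highest of 1045 called genes, the latter with 2 libraries exchanged at 1 time, and the rest are not tested. The split by replicate number gave 2. No other split that was run reached 3542.

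CA9 stood at 96.1 to 314 CPM in the NEE-sampled libraries, against 0.792 to 9.99 CPM in the monolayer lysates and 102 to 327 CPM in the spheroid lysates. ALDOC (log2 fold change 3.14) and NDRG1 (2.38) were also higher in NEE-sampled RNA than in monolayer lysate before NEE. Lower oxygen in the cultures sampled by NEE could not be decided, since the 25 other hypoxia and glycolysis genes had a median of 0.60 (95% interval −0.52 to 1.42), 9 of them called higher and 5 lower.

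Leukocyte transcripts of replicate 1 of the monolayers before NEE were found at low level in the other 15 lysate libraries. Over 19 genes of the natural killer and T cell list they stood at a median of 3.71% (quartiles 3.22 to 4.27) of their CPM in that library, with a Spearman rho across genes of 0.921, and at 0.14% in the NEE-sampled libraries. Whether they are reads exchanged between libraries during sequencing or RNA of the libraries themselves was not tested.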
